A study of Homo sapiens with 20 samples.

How the data were processed

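The samples were LNCaP cells, an established human prostate cancer line, on 20 Affymetrix human gene arrays: 3 per group in 6 groups and 2 in early S. Per the labels' protocols, RNA was extracted with Trizol, amplified with the NuGEN Ovation Pico WTA V2 kit and labelled with biotin. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between arrays. The deposited values were probe set intensities that the authors made with Affymetrix Expression Console 1.1, per the submitters' processing notes. The summary method and any normalization between arrays are not given in the sources used here. The values were settled as linear from the values themselves, with array medians of 5.44 to 9.09 and 0 values at or below 0. The design, written before the data were examined, allowed for either scale, and log2(value + 1) was used.

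The file held 33297 features. The platform's annotation table listed 21214 of them, 19460 with 1 gene symbol and 1754 with several, and 12083 were not listed. Features with several symbols or none were left out of the gene tests. Of the single-symbol ones, 19429 matched RefSeq for GRCh38.p14 by Entrez ID, which was used for current names only. Where a gene had several transcript clusters (769 genes), the one with the highest mean over all arrays was used, which gave 18417 genes tested. No 2 arrays were identical, and all 20 were used. Correlations between arrays used the brighter genes, and a residual score for each array was its position on the first principal component of the deviations from group means.

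Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 1 coefficient per group, all 20 arrays in 1 fit), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were CDT + DHT against CDT, each arrest against CDT, each arrest against CDT + DHT and each arrest against the mean of the other arrests, and a moderated F test among the 5 arrests. A gene was distinct in an arrest when it passed in all 4 pairwise contrasts in 1 direction. The 18 gene lists, all fixed in advance, were tested with camera at its preset correlation of 0.01, with adjustment over the 18 lists of a comparison: androgen-induced, androgen-repressed, G1/S replication, G2/M mitotic, replication-dependent histones, p53 targets, immediate early and short-lived, sterol synthesis, fatty acid synthesis, glycolysis, unfolded protein and amino acid stress, interferon-stimulated, NF-κB inflammatory, neuroendocrine, tubulins, and stromal, leukocyte and basal epithelial markers. Each list was also tested with a correlation estimated from the data. Within a list, genes were adjusted over the list alone as a second count. Exact permutation tests of the mean of a list over arrays, and of single genes in the arrays with DHT against CDT, were two-sided and were added after the data were seen. With 3 arrays against 3 such a test cannot go below 0.1, so none was made for pairs of groups.

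Genes were named by a rule set in advance: the 10 largest differences per direction among genes that passed and whose arrays did not overlap, up to 4 list members that passed and 2 that did not per list and comparison, the 10 most distinct genes per arrest, and, in any comparison, a fixed set with KLK3, KLK2, TMPRSS2, FKBP5, CCND1, CCNE1, CCNE2, CCNA2, CCNB1, CDK1, CDKN1A, MKI67, MCM5, PCNA and MYC. Other members of that set are not reported here. TMPRSS2 and FKBP5 had only features with several symbols and were not tested here.

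The fit was tested on simulated data with the spread of these arrays and genes drawn independently. For each comparison, 50 genes were changed at each of 4 step sizes, all in the same set. The fit recovered 0%, 8%, 38% and 64% of genes changed by 1, 2, 3 and 4 on the log2 scale in CDT + DHT against CDT, 0%, 10%, 32% and 70% in early S against CDT, 2%, 14%, 42% and 76% in G2/M against CDT, and 2%, 30%, 54% and 94% in late G1 against the other arrests. Of the calls, 6.78%, 8.20%, 4.29% and 3.23% were unchanged genes. With 1 list shifted and genes drawn independently, camera called 0 of 34 other lists. With the residual covariance of the arrays kept and no group changed, it called at least 1 of 18 lists in 52 of 100 sets at the preset correlation, in 45 with the residual score in the fit, and in 0 with the estimated correlation, with or without the score, a test added after the data were seen. Alternatives planned in advance were quantile normalization, centring of arrays, a filter on dim genes, the mean of a gene's clusters, every feature tested, eBayes with trend and robust, arrayWeights, the replicate number as a block, only the compared groups in the fit, the estimated correlation and leaving out each array. A pseudocount of 16, the residual score as a covariate (also together with the estimated correlation) and leaving out 4 arrays that stood apart were added after the data were seen.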

Results

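Gene expression was measured in LNCaP, a human prostate cancer cell line that responds to androgens, on 20 arrays in 7 groups. As the series title and design put it, the question was which transcripts under dihydrotestosterone (DHT), a potent natural androgen, depend on the phase of the cell cycle. The control, CDT, held cells kept for 72 h in a medium the labels call CDT and given ethanol for 3 h (n = 3). In CDT + DHT, cells from the same medium had DHT for 3 h (n = 3). The 5 arrested groups grew in hormone-proficient medium and had 10 nM DHT for the last 3 h. Early G1 was reached with PD-0332991, an inhibitor of the G1 kinases CDK4 and CDK6, at 0.5 µM for 24 h (n = 3). Late G1 was reached with roscovitine, which inhibits several cyclin-dependent kinases, at 5 µg/mL for 24 h (n = 3). Early S cells had aphidicolin, a DNA polymerase inhibitor, at 2 µg/mL for 24 h (n = 2), and late S cells had hydroxyurea, which depletes deoxynucleotides, at 1 mM for 24 h (n = 3). G2/M cells had 15 h of aphidicolin, a washout and then 9 h of nocodazole, which blocks microtubule assembly, at 50 ng/mL (n = 3). The phases are those the labels give. Arrested cells without DHT were not analysed here, so against CDT an arrest differs in DHT, drug and medium together.

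The median intensity of an array lay between 5.44 and 9.09. Over the 5879 brighter genes, arrays of one group correlated across genes at 0.608 to 0.948 (median 0.858 over 19 pairs), and arrays of different groups at 0.425 to 0.918 (median 0.779 over 171 pairs), with genes not being independent replicates. Groups held 35.8% of the total variance, a share not adjusted for the number of groups. With 7 groups and 20 arrays, most of such a share arises by chance. Of the variance left within groups, 29.2% lay on a single axis. Late S replicate 1 (score 2.40), CDT + DHT replicate 3 (1.54), CDT replicate 1 (1.35) and early G1 replicate 2 (1.33) lay farthest out on one side of that axis. All log2 differences below are given ± SE from 1 limma fit over the 20 arrays and 18417 genes, with p-values adjusted by Benjamini-Hochberg. The number of arrays limits their precision. Sizes also depend on the pseudocount of 1: with one of 16, an alternative added after the data were seen, 56 of 82 calls of named genes were smaller by more than 1.5 times and 13 did not pass, and 56 of 77 medians of called lists were smaller by as much. Calls of gene lists (camera) were checked in 100 simulated sets of unchanged groups with the residual covariance of these arrays, a test added after the data were seen. At the preset correlation of 0.01, at least 1 list was called in 52 of the sets, so a call at that correlation alone is weak. With an estimated correlation 0 sets had a call. With the residual score in the fit as well, 0 sets had one, and in that setting, also added after the data were seen, 32 of 73 list calls against CDT or among arrests held, and 14 of 27 against CDT + DHT.

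The kallikrein genes KLK2 and KLK3, the latter encoding prostate-specific antigen, are textbook androgen-induced genes, and with DHT alone, in CDT medium, KLK2 rose when adjusted over the androgen-induced list alone, while KLK3 passed no test. KLK2 lay at 5.75 ± 0.09 in CDT (log2 intensity, mean ± SD, n = 3) and at 7.90 ± 0.20 in CDT + DHT (n = 3), and KLK3 at 7.57 ± 0.91 and 8.76 ± 0.19. The limma differences, 2.15 ± 0.42 for KLK2 (adjusted p = 0.654) and 1.18 ± 0.50 for KLK3 (adjusted p = 0.696), did not pass over all genes, although the 3 arrays of each group did not overlap for either gene, which chance alone gives for 10% of genes. Set against all 17 arrays that had DHT, 14 of them arrested and in the other medium, CDT was lower by 2.51 for KLK2 and by 1.80 for KLK3, and all 17 lay above every CDT array for both genes. The exact permutation p was 0.000877 for each, the smallest that 1140 splits of the arrays allow, and 0.00570 after adjustment over the 13 genes tested this way, a test added after the data were seen. As a group, the androgen-induced genes (29 of 34 listed were measured) had a median difference of 0.79 in CDT + DHT, with 22 members above 0 (camera, adjusted p = 0.00334 over 18 lists). That call was lost at adjusted p = 0.894 with an estimated correlation, and at 0.0794 with the residual score in the fit as well. With a pseudocount of 16 the median was 0.21. Adjusted over the list alone, 2 members rose, KLK2 and RHOU (2.15 ± 0.60), a small GTPase gene.

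No gene passed in CDT + DHT against CDT over all genes with limma. An unadjusted p below 0.05 was found for 1263 genes (6.86%), where chance alone gives a share of 0.05. Such counts, given here for each comparison, are therefore no sign of change by themselves. Over the comparisons their share ran from 2.47% (early G1 against other arrests) to 15.09% (G2/M against CDT + DHT). Without CDT replicate 1, 2 genes were called. Glycolysis genes shifted up together (median 0.73, 13 of 18 above 0, adjusted p = 0.00334, and 0.894 with an estimated correlation), with GPI at 1.42 ± 0.58 and ENO1 at 1.25 ± 0.53, neither of which passed. Replication-dependent histone genes had a median of 0.53 (adjusted p = 0.00334, and 0.894 with an estimated correlation). Without CDT + DHT replicate 1 the histone call was lost (adjusted p = 0.0601). CCND1, which encodes the G1 cyclin D1, lay at 6.45 ± 0.96 in CDT and 4.95 ± 0.82 in CDT + DHT (adjusted p = 0.717). The sensitivity of this test was low: of genes simulated to change by 2 on the log2 scale in this comparison, 8% were recovered, and of those changed by 4, 64%.

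**Figure D1:**
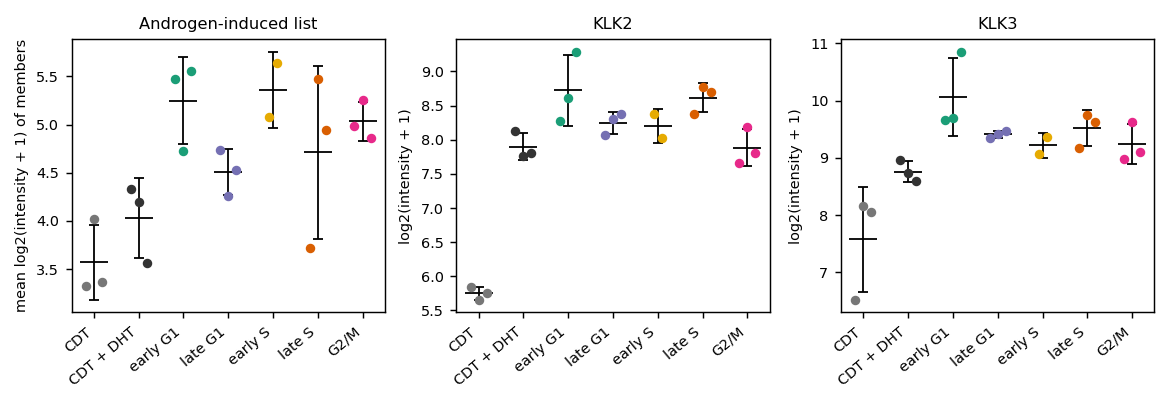
Mean log2(intensity + 1) of the androgen-induced list (left), KLK2 (middle) and KLK3 (right) in each of the 7 groups. Points are arrays, the long bar is the group mean and the whiskers are ± SD (n = 3, early S n = 2), and all 17 arrays with DHT lie above the 3 CDT arrays for KLK2 and KLK3.

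Androgen-induced genes had a higher median than in CDT in each of the 5 arrests, though in late S the arrays overlapped those of CDT. Their median difference was 1.65 in early G1, 0.81 in late G1, 1.91 in early S, 1.01 in late S and 1.60 in G2/M, with camera adjusted p between 2.2e-24 and 1.9e-08. With an estimated correlation the early G1 call held (adjusted p = 0.0280). The others were lost, at adjusted p = 0.328 in late G1, 0.0601 in early S, 0.117 in late S and 0.112 in G2/M with an estimated correlation. With the residual score in the fit as well, all 5 passed, at adjusted p = 1.4e-05 in early G1, 0.00171 in late G1, 3.4e-05 in early S, 9.4e-05 in late S and 6.3e-05 in G2/M. With a pseudocount of 16 the medians were 0.95, 0.32, 1.08, 0.49 and 0.75 in that order. Late S replicate 1 (list mean 3.72) lay below CDT replicate 2 (4.02). Some other splits of the late S and CDT arrays, given below, gave a median at least as large in size. Adjusted over the list alone, 15 of the 29 members rose in early G1, 8 in late G1, 18 in early S, 7 in late S and 13 in G2/M. KLK2 rose over all genes in early G1 by 2.97 ± 0.42 (7.85-fold, adjusted p = 0.0154), in late G1 by 2.50 ± 0.42 (adjusted p = 0.0147) and in late S by 2.87 ± 0.42 (adjusted p = 0.0102). Its difference was 2.45 ± 0.47 in early S (adjusted p = 0.10) and 2.13 ± 0.42 in G2/M (adjusted p = 0.0525). KLK3 did not pass over all genes in any arrest, with 2.49 ± 0.50 in early G1 (adjusted p = 0.440) as its largest difference. The mean of the list over its members was 3.57 ± 0.39 in CDT (n = 3) and 4.78 ± 0.62 over the 17 arrays with DHT, an exact permutation p of 0.00439 that became 0.0790 over the 18 lists.

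Against CDT + DHT, which had the hormone but neither the drugs nor the other medium, the androgen-induced median was 0.92 in early G1 (adjusted p = 1.2e-08), 1.03 in early S (8.4e-08), 0.54 in late S (0.00293) and 0.57 in G2/M (0.00036). With an estimated correlation none of these passed (adjusted p = 0.384, 0.248, 0.597 and 0.480), and with the residual score in the fit as well all 4 did (0.00472, 0.00488, 0.0381 and 0.0381). In late G1 the median was 0.43 and did not pass (adjusted p = 0.0731, and 0.365 in that last setting). With a pseudocount of 16 the medians were 0.67 in early G1, 0.22 in late G1, 0.69 in early S, 0.40 in late S and 0.34 in G2/M. Without late S replicate 2 the late S call was lost (adjusted p = 0.153), and without late G1 replicate 2 the late G1 difference passed (adjusted p = 0.0422). Late S replicate 1 (list mean 3.72) lay below CDT + DHT replicates 1 and 2 (4.335 and 4.192). Some other splits of the late S and CDT + DHT arrays, given below, gave a median at least as large in size. Whether the arrests differed from one another in these genes was tested against the mean of the other arrests. The list was higher in early G1 (0.36, adjusted p = 0.00618, and 0.571 with an estimated correlation) and lower in late G1 (-0.42, adjusted p = 0.00793, and 0.704 with an estimated correlation), where HOMER2, a scaffold gene, fell by 1.78 ± 0.39 over all genes. In early S the median was 0.56 (adjusted p = 0.0258, and 0.518 with an estimated correlation), and in late S (-0.39, adjusted p = 0.136) and G2/M (-0.04, adjusted p = 0.903) the list did not pass. None of the 3 calls held with an estimated correlation and the residual score in the fit (adjusted p = 0.0681, 0.0987 and 0.288). The calls in early G1, late G1 and early S were each also lost without 1 array: early G1 replicate 1 (adjusted p = 0.139), late G1 replicate 2 (0.0952) and early S replicate 2 (0.587), the early S call also without late G1 replicate 2 (0.0528).

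In early G1 against CDT, KLK2 was the single gene that passed over all genes with limma (1 up, 0 down), and 942 had an unadjusted p below 0.05. Among androgen-induced genes adjusted over the list alone, TIPARP, an ADP-ribosyltransferase gene, rose by 3.32 ± 0.72, and SGK1, a serum- and steroid-regulated kinase gene, by 3.14 ± 0.70. Sterol synthesis genes shifted up (median 0.91, 17 of 19 above 0, adjusted p = 2.7e-06, and 0.213 with an estimated correlation), with IDI1 at 1.87 ± 0.78, below the threshold. Fatty acid synthesis genes had a median of 0.70 (adjusted p = 0.00836, and 0.339 with an estimated correlation), FASN lying at 1.47 ± 0.57, and their call was lost without early G1 replicate 3 (adjusted p = 0.0509) or CDT replicate 1 (0.0638). Immediate early genes shifted down (median -0.48, adjusted p = 0.00117, and 0.213 with an estimated correlation), and ID3, an inhibitor of basic helix-loop-helix factors, fell by 1.87 ± 0.45 adjusted over the list alone. Mitotic genes had a median of 0.36 (adjusted p = 0.00690, and 0.636 with an estimated correlation), which turned to -0.05 without CDT replicate 1 and was lost without early G1 replicate 1 (adjusted p = 0.582). The count of 1 gene was 0 without early G1 replicate 2 or 3 or any CDT array, and with only the compared groups in the fit, and with a pseudocount of 16 there were 3 genes higher and 10 lower. Apart from androgen-induced genes, sterol synthesis was the single list of this comparison that held with an estimated correlation and the residual score in the fit (adjusted p = 0.00842). The sterol rise was not particular to early G1. At the preset correlation it was also called against CDT in early S (median 0.89), late S (0.69) and G2/M (0.67).

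Against the other arrests, early G1 had lower p53 target genes, the set that the p53 protein switches on after DNA damage (median -0.48, 22 of 25 at or below 0, adjusted p = 1.2e-11). The adjusted p was 0.0796 with an estimated correlation. Adjusted over the list alone, 5 fell, among them TP53I3 (-2.73 ± 0.48), CDKN1A (-2.55 ± 0.47), which encodes the kinase inhibitor p21, and DDB2 (-1.83 ± 0.35), a DNA repair gene. CDKN1A lay at 5.21 ± 0.99 in early G1, near the CDT level of 4.98 ± 1.23, and at 8.49 ± 0.08 in early S and 8.85 ± 0.48 in late S. Genes of the NF-κB inflammatory list were lower too (median -0.54, adjusted p = 6.3e-05, and 0.0501 with an estimated correlation), CCL20, a chemokine gene, falling by 1.99 ± 0.55 adjusted over the list alone. Interferon-stimulated genes had a median of -0.44 (adjusted p = 0.0102, and 0.0796 with an estimated correlation), a call that was lost without early G1 replicate 3 (adjusted p = 0.123). Mitotic genes were not set apart (median 0.08, adjusted p = 0.556), and MKI67, the gene of the proliferation marker Ki-67, differed by 0.15 ± 0.61. p53 targets (adjusted p = 0.000148), the interferon list (0.0230) and the NF-κB list (0.0321) held with an estimated correlation and the residual score in the fit. So did replication genes (median -0.215, adjusted p = 0.00618 at the preset correlation and 0.0230 in that setting), but their median turned to 0.18 without early G1 replicate 2. Histones (median 0.34), sterol synthesis (0.35), tubulins (0.31) and immediate early genes (-0.12) were called at the preset correlation and did not hold in that setting. No gene passed over all genes with limma in this comparison. An unadjusted p below 0.05 was found for 455 genes (2.47%), under the share of 0.05 that chance gives.

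Late G1 against CDT was marked by lower mitotic genes, and as a list tubulin genes were lower at the preset correlation only. CDC25B, a phosphatase that activates mitotic cyclin-dependent kinase, fell by 4.71 ± 0.55 (adjusted p = 0.000963), and PLK1, a kinase of mitotic entry, by 4.03 ± 0.55 (adjusted p = 0.00319). TUBA1A, an alpha-tubulin gene, fell by 3.34 ± 0.42 and POLR2A, which encodes the largest subunit of RNA polymerase II, by 3.47 ± 0.52 (adjusted p = 0.00176 and 0.00725). In all, 1 gene rose (KLK2) and 18 fell over all genes, and 1669 had an unadjusted p below 0.05. Mitotic genes had a median of -1.06, 3 of the 55 falling over all genes (PLK1, BIRC5 and CDCA3, the last not with a pseudocount of 16) and 15 adjusted over the list alone (adjusted p = 2.9e-09, and 0.430 with an estimated correlation). Tubulins had a median of -1.16, 1 and 6 of 11 falling in the same counts (adjusted p = 1.2e-07, and 0.185 with an estimated correlation). Replication genes (median -0.60, adjusted p = 0.00163) and histones (-0.66, adjusted p = 7.4e-05) were lower as groups, with RRM2, a ribonucleotide reductase subunit gene, falling by 2.81 ± 0.49 over all genes. Those calls gave adjusted p = 0.601 and 0.466 with an estimated correlation. Immediate early genes had a median of -0.61 (adjusted p = 0.00923, and 0.405 with an estimated correlation), IER3 lying at -2.93 ± 0.57 (adjusted p = 0.0516). Of these lists, mitotic (adjusted p = 0.00171) and replication genes (0.0193) held with an estimated correlation and the residual score in the fit.

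The count of 19 in late G1 against CDT was 4, 6 and 10 without CDT replicates 1, 2 and 3, and 4 without late G1 replicate 3. With only the compared groups in the fit it was 0, so none of these calls held there. When arrays were left out of the full fit, CDC25B, PLK1 and TUBA1A stayed past the threshold whichever one it was, and RTN1 (-3.65 ± 0.55), a reticulon gene, in 5 of 6 cases.

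Against the other arrests, late G1 had 3 genes higher and 127 lower over all genes (limma), 1942 having an unadjusted p below 0.05. SFN, which encodes 14-3-3 sigma, a p53-regulated inhibitor of mitotic entry, lay lower by 5.37 ± 0.48 (adjusted p = 1.2e-05). Its difference was -2.77 with a pseudocount of 16, since late G1 lay near the floor. SFN was also called higher than CDT in 3 of those other arrests, namely early S, late S and G2/M. CDC25B fell by 4.47 ± 0.44 (adjusted p = 3.2e-05). The mitotic list had a median of -2.00, 17 of its 55 members falling over all genes and 33 adjusted over the list alone (adjusted p = 1.7e-31, and 0.135 with an estimated correlation, where the call was lost). Among them were PLK1 (-3.73 ± 0.44), BIRC5 (-3.09 ± 0.37), which encodes survivin, and CDCA3 (-3.40 ± 0.41), and by size TOP2A (-4.24 ± 0.65), the DNA topoisomerase II alpha gene. CCNB1, the cyclin B1 gene, fell by 1.78 ± 0.38 (adjusted p = 0.0323) and MKI67 by 3.65 ± 0.61 (adjusted p = 0.00514), while CDK1 lay at -2.44 ± 0.64 (adjusted p = 0.0918). Averaged over the list, the 3 late G1 arrays lay below all 11 others (2.95 ± 0.23 against 4.84 ± 0.86, exact permutation p = 0.00275, the smallest that 364 splits allow, adjusted p = 0.247 over 90 such tests), and CDT lay at 4.09 ± 0.70. A single test at that smallest p cannot pass over 90 tests, so the adjusted value does not speak against the separation of the arrays.

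Other groups fell with them in late G1. Replication genes had a median of -1.17, 5 of 44 falling over all genes and 15 adjusted over the list alone (adjusted p = 9.9e-15, and 0.135 with an estimated correlation), among them RRM2 (-3.58 ± 0.39), RAD51AP1 (-3.36 ± 0.55) and CDC45 (-2.88 ± 0.50), which act in nucleotide supply, recombination repair and origin firing. MCM5, a subunit of the replicative helicase, differed by 0.31 ± 0.55 and did not pass. Histones had a median of -1.08, 3 of 47 falling over all genes (H1-2, H2BC5 and H2AC11, the last not with a pseudocount of 16) and 19 adjusted over the list alone (adjusted p = 1.3e-12, and 0.135 with an estimated correlation). Tubulins had a median of -0.89, TUBA1B falling by 2.06 ± 0.39 over all genes and 5 of 11 adjusted over the list alone (adjusted p = 2.3e-05, and 0.135 with an estimated correlation). For p53 targets the median was -1.06 with 0 of 25 passing over all genes and 4 lower adjusted over the list alone (adjusted p = 0.000298, and 0.507 with an estimated correlation). Set against CDT, p53 targets were not lower in late G1 (median 0.002, camera adjusted p = 0.438). IER3, an immediate early gene, fell by 3.74 ± 0.46 over all genes, but its list did not pass (median -0.11, adjusted p = 0.418). Fatty acid synthesis (median -0.62, adjusted p = 0.0310, with FADS2, a fatty acid desaturase gene, falling by 1.87 ± 0.43) and sterol synthesis (-0.23, adjusted p = 0.0415) passed, and gave 0.623 and 0.727 with an estimated correlation. Fatty acid and sterol synthesis calls were lost without late G1 replicate 3 (adjusted p = 0.247 and 0.210), late G1 replicate 2 (0.0952 and 0.189), early S replicate 2 (0.0691 and 0.0977), late S replicate 2 (0.0548 and 0.0778) or late S replicate 3 (0.0513 each). The sterol call was also lost without G2/M replicate 3 (0.0552), early G1 replicate 1 (0.0614) or early G1 replicate 3 (0.0655). Of the lists lower in late G1, mitotic genes (adjusted p = 1.1e-05), replication genes (4.7e-05) and p53 targets (0.0176) held with an estimated correlation and the residual score in the fit, and histones (0.125) and tubulins (0.140) did not. The 3 genes higher were ASL (2.27 ± 0.45), an arginine-synthesis enzyme gene, RGS11 (2.18 ± 0.40), a regulator of G-protein signalling, and AIFM3 (1.97 ± 0.42).

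Of the 130 genes, 93 had late G1 arrays that did not overlap the 11 others. For a gene not picked by its difference, chance gives that in 2 of 364 splits. The 130 were picked for differing on these same arrays, so the 93 are no separate support. The count was 81 with only the compared groups in the fit, 230 without late S replicate 1, 80 without G2/M replicate 2, and 73, 76 and 33 without late G1 replicates 1, 2 and 3. SFN, CDC25B, PLK1, BIRC5, CDCA3, RRM2 and IER3 passed whichever array was left out.

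**Figure D2:**
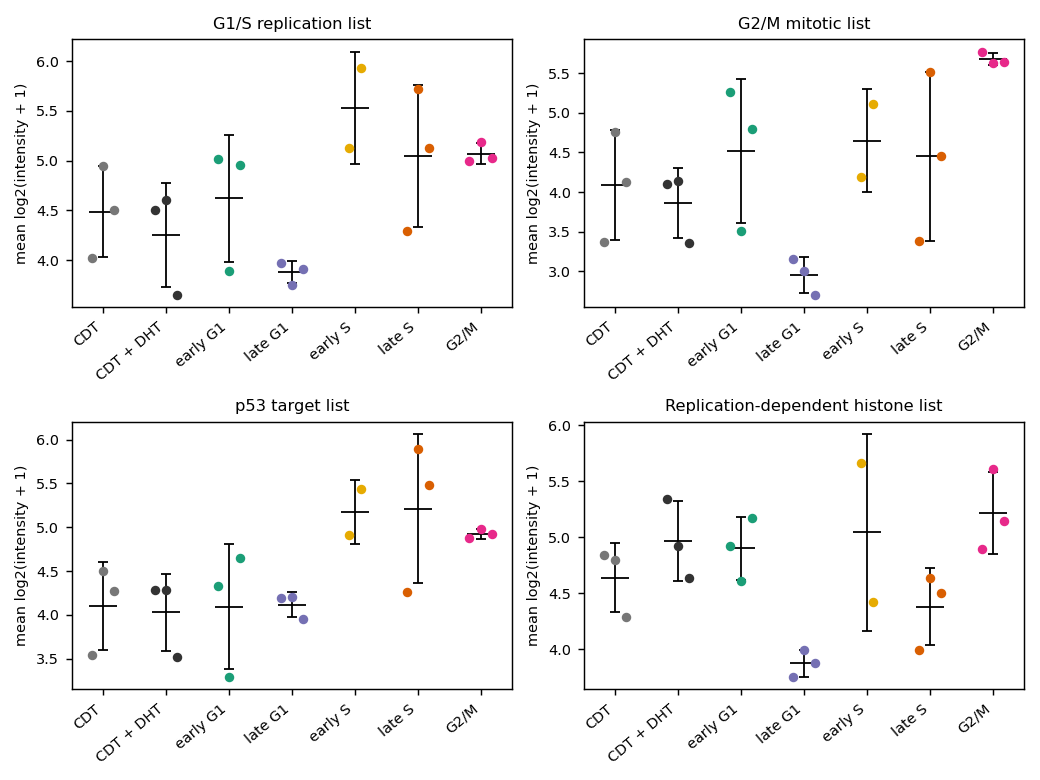
Mean log2(intensity + 1) of the G1/S replication, G2/M mitotic, p53 target and replication-dependent histone lists in each group. Points are arrays, the long bar is the group mean and the whiskers are ± SD (n = 3, early S n = 2), and the mitotic list is lowest in late G1 (2.95 ± 0.23) and highest in G2/M (5.68 ± 0.08).

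Early S against CDT had 2 genes higher and 4 lower over all genes (limma), with 1026 at an unadjusted p below 0.05. S100P, a calcium-binding protein gene, rose by 5.04 ± 0.81 (adjusted p = 0.0205) and SFN by 4.73 ± 0.66 (adjusted p = 0.00618; 3.08 with a pseudocount of 16). ACKR3, an atypical chemokine receptor gene on the androgen-repressed list, fell by 3.73 ± 0.59 (adjusted p = 0.0205), and ZSWIM4 by 3.90 ± 0.55, PPP2R5B by 3.32 ± 0.57 and the olfactory receptor gene OR1G1 by 5.11 ± 0.60. Both early S arrays listed OR1G1 near 0 on the log2 scale (0.01 ± 0.01), so the size of its change depends on the pseudocount. p53 targets shifted up (median 0.91, 23 of 25 above 0, adjusted p = 6.4e-07, and 0.271 with an estimated correlation). Of them 0 passed over all genes and 3 rose adjusted over the list alone, CDKN1A (3.51 ± 0.66) and TP53I3 (3.24 ± 0.68) included. Replication genes shifted up (median 1.11, 39 of 44 above 0, adjusted p = 5.3e-09, and 0.271 with an estimated correlation), with CDC6, a licensing factor gene, at 2.77 ± 0.76 and RRM2 at 1.87 ± 0.54, neither past the threshold. Glycolysis genes had a median of 0.95 (adjusted p = 0.00505, and 0.361 with an estimated correlation), TPI1 lying at 1.31 ± 0.59. Against CDT + DHT they were not higher in early S (median -0.03, camera adjusted p = 0.909), and CDT + DHT itself had a median of 0.73 against CDT. Sterol synthesis genes had a median of 0.89 (adjusted p = 0.00505, and 0.361 with an estimated correlation). That sterol call was lost without CDT replicate 1 (adjusted p = 0.152). Replication genes (adjusted p = 0.000783) and p53 targets (0.00234) held with an estimated correlation and the residual score in the fit.

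Without early S replicate 1, or with only the compared groups in the fit, no gene was called, and without early S replicate 2, CDT replicate 1 or CDT replicate 3 the count was 3 each. With arrays centred on their medians, 7 genes were higher and 4 lower, and after quantile normalization 4 and 4. Against the other arrests, early S had no gene past the threshold with limma. An unadjusted p below 0.05 was found for 714 genes (3.88%), under the share of 0.05 that chance gives. Tubulins were higher as a group (median 0.63, all 11 above 0, adjusted p = 0.00189, and 0.338 with an estimated correlation), and adjusted over the list alone TUBB rose by 1.63 ± 0.52 and TUBA1B by 1.37 ± 0.45. Replication genes had a median of 0.89 (adjusted p = 8e-09, and 0.338 with an estimated correlation), RRM2 rising by 2.26 ± 0.45 adjusted over the list alone. Without early S replicate 2 the replication call was lost (adjusted p = 0.0974), as were those of p53 targets (0.560, from 0.0123 at a median of 0.43, and 0.492 with an estimated correlation), and without either early S array those of immediate early genes (0.0707 and 0.0757, from 0.00797 at a median of 0.57, and 0.338 with an estimated correlation). Histones had a median of 0.50 (adjusted p = 0.00467, and 0.492 with an estimated correlation), which turned to -0.10 without early S replicate 1. Of these lists only replication genes held with an estimated correlation and the residual score in the fit (adjusted p = 0.00201).

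Late S against CDT had 18 genes higher and 0 lower over all genes (limma), with 1094 at an unadjusted p below 0.05. That direction was not kept throughout, with 106 higher and 99 lower with arrayWeights, and 20 and 16 with a pseudocount of 16. SFN rose by 5.55 ± 0.59 (adjusted p = 0.000257; 3.85 with a pseudocount of 16, since CDT lay low at 2.75 ± 1.34) and S100P by 4.93 ± 0.73 (adjusted p = 0.0102). Of 25 p53 targets, 4 rose over all genes, namely CDKN1A (3.88 ± 0.59), TP53I3 (3.76 ± 0.60), DDB2 (2.53 ± 0.44) and GDF15 (2.53 ± 0.44), a stress cytokine gene, and 6 adjusted over the list alone. The list median was 1.00 (adjusted p = 4.9e-12, and 0.117 with an estimated correlation). IER3 rose by 3.44 ± 0.57 (adjusted p = 0.0254) although the median of its immediate early list was -0.58 (adjusted p = 0.0480, and 0.458 with an estimated correlation), a call lost without CDT replicate 1 (adjusted p = 0.229), CDT replicate 2 (0.0816) or late S replicates 1, 2 and 3 (0.0773, 0.178 and 0.0664). Replication genes had a median of 0.63 (36 of 44 above 0, adjusted p = 2.2e-05, and 0.458 with an estimated correlation). Androgen-repressed genes had a median of -0.45 (adjusted p = 0.0230, and 0.181 with an estimated correlation), and CAMK2N1 (-2.10 ± 0.42) and ACKR3 (-1.77 ± 0.53) fell adjusted over the list alone. That list call was lost without late S replicate 2 (adjusted p = 0.152), CDT replicate 1 (0.0753) or CDT replicate 2 (0.0659). p53 targets (adjusted p = 9.4e-05), replication genes (0.00101) and androgen-repressed genes (0.0386) held with an estimated correlation and the residual score in the fit. So did sterol synthesis (median 0.69, adjusted p = 0.0101), mitotic (0.32, 0.0253) and fatty acid synthesis genes (0.38, 0.03035), none passing with an estimated correlation alone. Without CDT replicate 1 their calls at the preset correlation were lost (0.110, 0.776 and 0.143), the mitotic median turning to -0.12. Other genes in the 10 with the largest differences, such as C8A (5.89 ± 1.04), a complement component gene, and OR51M1 (5.11 ± 0.94), lay near 0 in CDT (0.32 ± 0.53 and 0.21 ± 0.20), and neither passed with a pseudocount of 16.

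The count of 18 was 5, 35 and 1 without late S replicates 1, 2 and 3, and 6, 4 and 1 without CDT replicates 1, 2 and 3, and SFN alone of the genes named here for late S against CDT passed in all 6 cases. With only the compared groups in the fit no gene passed. Against the other arrests, 5 genes rose in late S and 0 fell over all genes (limma), with 1275 at an unadjusted p below 0.05. The direction was not one-sided throughout, with 6 higher and 7 lower without late S replicate 2, and 335 higher and 535 lower with arrayWeights. These were IER3 (4.21 ± 0.46), SFN (3.57 ± 0.48, and 2.55 with a pseudocount of 16), HMOX1 (2.76 ± 0.40), the heme oxygenase gene induced by oxidative stress, GSN (2.60 ± 0.40), which encodes the actin-severing protein gelsolin, and OR1G1 (2.70), whose arrays overlapped those of the other arrests, which did not pass with a pseudocount of 16 and which is named only because the count is small. p53 targets were higher as a group (median 0.47, adjusted p = 2.4e-06, and 0.378 with an estimated correlation), 6 of 25 rising adjusted over the list alone, among them BBC3 (2.04 ± 0.40), a pro-apoptotic gene, and GDF15 (1.80 ± 0.36). Histones were lower (median -0.45, adjusted p = 0.00181, and 0.623 with an estimated correlation), a call lost without late S replicate 2 (adjusted p = 0.0675) or early S replicate 1 (0.0936). Tubulins had a median of 0.40 (adjusted p = 0.00181, and 0.378 with an estimated correlation), and lost it without late S replicate 3 (adjusted p = 0.0573). Of these 3 lists only p53 targets held with an estimated correlation and the residual score in the fit (adjusted p = 0.00028). Replication genes were called too (median 0.27, adjusted p = 0.0123, and 0.680 with an estimated correlation) and held in that setting (0.00265). Their call at the preset correlation was lost without late S replicate 2 (0.527), late S replicate 3 (0.0779) or early G1 replicate 2 (0.0727). The count of 5 was 2, 13 and 1 without late S replicates 1, 2 and 3, and 8 without early G1 replicate 3.

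**Figure D3:**
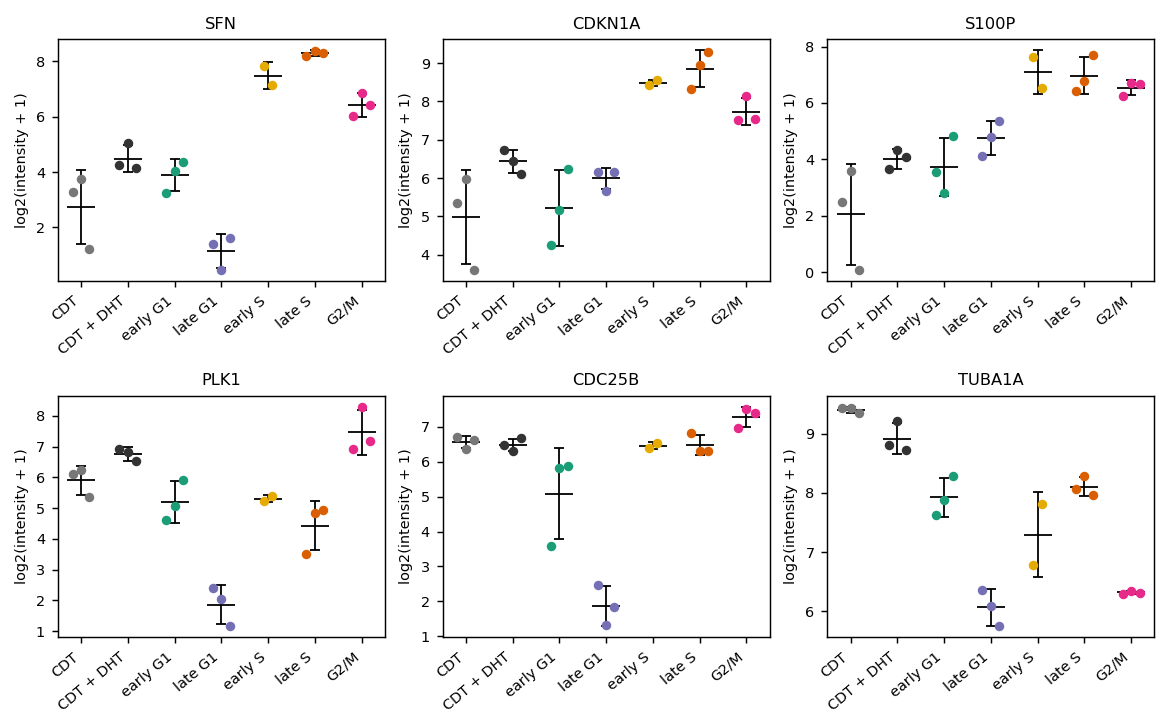
Log2(intensity + 1) of SFN, CDKN1A, S100P, PLK1, CDC25B and TUBA1A in each group. Points are arrays, the long bar is the group mean and the whiskers are ± SD (n = 3, early S n = 2), and SFN runs from 1.16 ± 0.61 in late G1 to 8.30 ± 0.10 in late S.

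G2/M against CDT had 9 genes higher and 11 lower over all genes (limma), with 1298 at an unadjusted p below 0.05. TUBA1A fell by 3.09 ± 0.42 (adjusted p = 0.00554) and TUBB4A, a beta-tubulin gene, by 3.14 ± 0.54 (adjusted p = 0.0242), within a tubulin list whose median was -0.61, with 10 of 11 below 0 and 4 lower adjusted over the list alone (adjusted p = 2.8e-06, and 0.117 with an estimated correlation). S100P rose by 4.50 ± 0.73, DHRS2, a short-chain dehydrogenase gene, by 4.11 ± 0.71, SFN by 3.69 ± 0.59 (2.15 with a pseudocount of 16) and TP53I3 by 3.34 ± 0.60. ZEB1, a repressor of epithelial genes, fell by 2.96 ± 0.51 and the kallikrein gene KLK6 by 3.16 ± 0.57, which did not pass with a pseudocount of 16. Mitotic genes shifted up (median 1.61, 53 of 55 above 0, adjusted p = 1.1e-25, and 0.117 with an estimated correlation). None passed over all genes, and 22 rose adjusted over the list alone, such as AURKA (2.56 ± 0.63), a spindle kinase gene, and HJURP (2.69 ± 0.74), a centromere chaperone gene. Histones (median 0.61, adjusted p = 1.7e-06), replication genes (0.61, 7.1e-05), p53 targets (0.65, 5e-06) and fatty acid synthesis genes (0.29, 0.00797) were also higher as groups, at adjusted p = 0.287, 0.356, 0.287 and 0.352 with an estimated correlation. Sterol synthesis genes had a median of 0.67 (adjusted p = 0.00112, and 0.352 with an estimated correlation), a call lost without CDT replicate 1 (adjusted p = 0.0733). Mitotic genes (adjusted p = 3.5e-05), p53 targets (0.00462) and replication genes (0.00915) held with an estimated correlation and the residual score in the fit. So did fatty acid and sterol synthesis (0.0482 each), while histones (0.247) and tubulins (0.102) did not. With the score, the median of fatty acid genes fell to 0.125 and that of replication genes to 0.372. On the fatty acid list ELOVL7, an elongase gene, lay at 4.52 ± 0.91 (adjusted p = 0.0567) and rose adjusted over the list alone.

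The count of 20 was 3, 3 and 5 without G2/M replicates 1, 2 and 3, and 3, 9 and 4 without CDT replicates 1, 2 and 3. TUBA1A and OR1G1 (-5.09 ± 0.53, near 0 in every G2/M array) passed in all 6 cases. With only the compared groups in the fit, 10 genes were higher and 1 lower, TUBA1A and SFN not among them. With arrays centred on their medians, 18 were higher and 12 lower. Against the other arrests, 4 genes rose in G2/M and 1 fell over all genes (limma), with 920 at an unadjusted p below 0.05. DHRS2 rose by 4.62 ± 0.57 (adjusted p = 0.00226), PLK1 by 3.26 ± 0.44 (adjusted p = 0.00407), AURKA by 3.02 ± 0.50 (adjusted p = 0.0404) and DEFB114, a defensin gene near 0 in most other arrays, by 2.63 ± 0.45 (adjusted p = 0.0495). OR1G1 fell by 2.93, with overlapping arrays, and is named only because the count is small. Neither DEFB114 nor OR1G1 passed with a pseudocount of 16. The mitotic list had a median of 1.64, 2 of 55 rising over all genes and 29 adjusted over the list alone (adjusted p = 2.2e-39, and 0.0722 with an estimated correlation), TPX2, a spindle assembly gene, rising by 2.71 ± 0.51 and CCNB1 by 1.81 ± 0.38 in the latter. All 3 G2/M arrays lay above the 11 others on the list mean (5.68 ± 0.08 against 4.10 ± 1.00, exact permutation p = 0.0192, adjusted p = 0.247 over 90 tests, in which no single test could pass by itself). Histones were higher (median 0.70, adjusted p = 1.3e-11) and tubulins lower (-0.32, adjusted p = 0.000198), 4 of the 11 tubulins falling adjusted over the list alone, TUBB4A by 2.32 ± 0.44. These gave adjusted p = 0.249 and 0.270 with an estimated correlation. Genes of unfolded protein and amino acid stress had a median of -0.25 (adjusted p = 0.0118, and 0.782 with an estimated correlation), a call lost without G2/M replicate 3 (adjusted p = 0.128) or early S replicate 2 (0.0643). The mitotic list alone held with an estimated correlation and the residual score in the fit (adjusted p = 3.5e-06). The count of 5 was 2, 0 and 2 without G2/M replicates 1, 2 and 3, and 3 without early S replicate 1, late S replicate 3, early G1 replicate 3, late G1 replicate 1 or late G1 replicate 3.

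Against CDT + DHT, limma called 0 genes in early G1 (1486 with an unadjusted p below 0.05), 5 higher and 90 lower in late G1 (2580), 0 higher and 1 lower in early S (1404), 10 higher and 3 lower in late S (1878), and 50 higher and 31 lower in G2/M (2779), counts for which no array was left out. Across the 5 arrests, 47 genes differed by the moderated F test of limma, and 1269 had an unadjusted p below 0.05. Of the 47, 39 were lowest in late G1, and 23 were highest in G2/M, 17 in late S and 6 in early S. The count was 25 without late S replicate 3, 27, 31 and 27 without G2/M replicates 1, 2 and 3, and 21, 18 and 14 without late G1 replicates 1, 2 and 3. No gene passed in all 4 pairwise contrasts of any arrest in 1 direction, and without late S replicate 1 there were 6 such genes, all lower in late G1, as were 2 without late G1 replicate 1 and 1 each without G2/M replicate 1, early G1 replicate 1 or late G1 replicate 2.

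Genes called against CDT were shared between arrests. KLK2 rose in 3 arrests, SFN and S100P in 3, and TP53I3 and C8A, among others, in 2, and TUBA1A, OR1G1 and ZSWIM4 fell in 2. Late S (18 higher) and G2/M (9 higher) shared 6 genes, against 0.00880 for independent lists and 0 in each of 50 simulations of unchanged groups set against the same CDT arrays, a value nearly fixed at 0 because unchanged groups call few genes. Over all genes their differences had a covariance of 0.35, against 0.30 in the simulations. Early S and G2/M shared 2 genes higher and 2 lower, with 0.000977 and 0.00239 for independent lists and 0 in the simulations, and a covariance of 0.44 against 0.30. Early S and late S, which shared SFN and S100P, had a covariance of 0.28, and late G1 and late S, which shared KLK2, of 0.29, each below the simulated 0.30. The 3 CDT arrays cannot be split with 2 on each side, so part of the sharing may come from the shared controls.

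No list of markers of other cell types passed in the comparisons against CDT or among arrests. The lowest adjusted p over all comparisons was 0.0929 for stromal markers (late G1 against CDT, median -0.45), 0.161 for leukocyte markers (early G1 against CDT, -0.21) and 0.224 for basal epithelial markers (early S against other arrests, 0.30). With arrays permuted, basal epithelial markers were higher in both early S arrays than in all 12 others (3.36 ± 0.09 against 2.91 ± 0.25, exact p = 0.0220, adjusted p = 0.247 over 90 tests, in which no single test could pass by itself), and stromal markers lower in the 17 arrays with DHT than in CDT (exact p = 0.0456, adjusted p = 0.322). Neuroendocrine genes passed once, in early S against CDT + DHT (median -0.89, adjusted p = 0.0217, and 0.238 with an estimated correlation).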

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

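The tests of a batch by replicate number, of the share of dim features, of the residual score as a covariate, of the short-lived list and of the medium were chosen only after the results were seen. Pairs of arrests were compared list by list, and 20 of 180 list and pair tests passed with arrays apart and a median difference of 1 or more, which is what singled them out as differences between groups. None passed with an estimated correlation. Early G1 lay above late G1 in mitotic genes (1.62), histones (1.1) and tubulins (1.05). It lay away from early S in replication genes (-1.06) and p53 targets (-1.04), and from G2/M in mitotic genes (-1.17). Late G1 minus early S gave -1.69 for replication genes, -1.82 for mitotic genes, -1.29 for histones, -1.18 for p53 targets and -1.23 for tubulins. Late G1 minus late S gave -1.06 for replication genes, -1.51 for mitotic genes, -1.17 for p53 targets and -1.32 for tubulins. Late G1 minus G2/M gave -1.23 for replication genes, -2.87 for mitotic genes and -1.30 for histones. Tubulins differed by 1.07 between early S and G2/M, and mitotic genes by -1.36 between late S and G2/M. Groups of 3 arrays were not tested for single arrays far from the others.

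Signals were also present in features outside the tested genes. These had no gene symbol, had several, or were further transcript clusters of tested genes. Against CDT, 3 such features passed in early G1, 11 in late G1, 2 in early S, 3 in late S and 7 in G2/M, and against the other arrests 40 passed in late G1 and 3 in late S. Of the 40, 22 were not listed in the annotation and 7 had several symbols.

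Arrays of one group differed along 1 shared axis that held 29.2% of the residual variance. Normalization between arrays was argued against by 27.71% after quantile normalization. Noise of the dimmest 33.3% of genes alone was argued against by 38.38% without them. Many genes that remained were dim too, as 5879 of the 18417 counted as brighter, so noise near the floor in those was not tested. A batch shared by arrays of the same replicate number was argued against by a median correlation of their deviations of -0.00512. The score on the axis went with the percent of features below an intensity of 1 over the 20 arrays (Pearson correlation 0.689, Spearman 0.666), a loose trend. CDT replicate 1 and early G1 replicate 2, both far out, had 15.36% and 16.92%, and G2/M replicate 1 and late G1 replicate 1, near the middle, had 19.18% each. Whether array quality or the cells lie behind the axis stays open. No biological explanation was tested.

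Mitotic transcripts were lower in late G1, under roscovitine, than in the other arrests, while in early G1, under PD-0332991, they were not set apart. Array quality along the shared axis was argued against by a median of -1.88 with the residual score as a covariate (adjusted p = 1.1e-05 with an estimated correlation), and a single late G1 array by a median of -1.887 in the case closest to 0. A general loss of short-lived transcripts as the whole cause was argued against by a median of -0.1084 for the immediate early list (quartiles -0.65 and 0.25). Against CDT that list was lower in late G1 (median -0.61, camera adjusted p = 0.00923, and 0.405 with an estimated correlation), beside -1.06 for mitotic genes. A part played by such a loss therefore stays open. What lowered these transcripts stays open. Position in the cycle was not tested, since the phases rest on the labels, and effects of roscovitine on kinases of transcription were not tested either. In early G1 neither mitotic (median 0.36, and -0.05 without CDT replicate 1) nor replication genes (0.20) lay below CDT with all arrays. The position of the CDT cells in the cycle is not known here, so that comparison decides nothing about the early G1 cells.

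Androgen-induced genes were higher in 4 of the 5 arrests than in CDT + DHT by camera at its preset correlation, late G1 not passing (adjusted p = 0.0731), and in none with an estimated correlation (adjusted p of 0.248 to 0.709). The preset correlation calls too many lists in simulated unchanged groups. Array quality along the shared axis as the whole cause was argued against in these 4, which all stayed above 0 and passed at the preset correlation with the residual score as a covariate: early G1 at 0.80 (adjusted p = 3.6e-08), early S at 0.695 (3.5e-07), late S at 0.53 (0.00056) and G2/M at 0.4107 (0.00102), the lowest. With an estimated correlation and the score they passed too (adjusted p of 0.00472 to 0.0381). A part in the size stays open, as early S went from 1.03 to 0.695. For late G1, at 0.3357 with the score (adjusted p = 0.110), nothing decides, because it had not passed without the score. The hormone-proficient medium instead of 72 h in CDT cannot be told apart from the arrests at the lowest median of 0.4333, because every arrested group had that medium and neither group in CDT did. Hormone in that medium before the 3 h of DHT stays open, as do the drugs and the cell cycle.

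Other splits of the arrays were counted for each comparison of 3 arrays with 3. As many genes as in the real split were called in 10 of 10 splits for CDT + DHT against CDT (0 genes), and in 1 of 10, the real one, for early G1 (1), late G1 (19), late S (18) and G2/M (20), with 0 in every other split. For the androgen-induced list a median as far from 0 was found in 2 of 10 splits for CDT + DHT, 1 for early G1, 1 for late G1, 3 for late S and 1 for G2/M against CDT, and in 1, 1, 5 and 1 for early G1, late G1, late S and G2/M against CDT + DHT. The highest medians of the other splits were 0.85, 1.03, 0.67, 1.305 and 0.86 against CDT, beside 0.79, 1.65, 0.81, 1.01 and 1.60 for the real ones, and 0.82, 0.41, 0.92 and 0.45 against CDT + DHT, beside 0.92, 0.43, 0.54 and 0.57. With 10 splits no share under 0.05 can be reached. Among 100 groupings of the 14 arrested arrays, as many genes were called in 100 for early G1 (0 genes), 2 for late G1, 4 for late S, 4 for G2/M and 1 for the F test (47 genes, 19 at most in another grouping). Some groupings called up to 111, 236, 376 and 321 genes where the real early G1, late G1, late S and G2/M gave 0, 130, 5 and 5. That points to a structure of the samples, whether of the arrests mixed in a grouping or of another kind, which was not tested.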

How the results depend on the processing

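The pseudocount of 16, the residual score as a covariate (also with the estimated correlation), the simulated unchanged groups and leaving out 4 arrays were tests chosen only after the results were seen. Of the 82 calls of named genes none reversed, and 75 were kept with quantile normalization, 80 with centring, 81 with the mean of clusters, 80 with trend and robust, 82 with arrayWeights, 31 with only the compared groups, 69 with a pseudocount of 16, 82 with the residual score and 45 without 4 arrays. Of 77 list calls, 67 to 77 were kept in each setting except the estimated correlation, which kept 1, or 36 with the residual score in the fit as well. Among those 36 are all androgen-induced calls but that of CDT + DHT against CDT (median 0.8048, adjusted p = 0.0794) and the ones among arrests. In simulated unchanged groups the preset correlation gave an unadjusted p below 0.05 in 14.67% of list tests, the estimated one in 0.61%, and with the score in 11.44% and 1.28%. Signal close to the floor limited the dim genes, whose differences depend on the pseudocount. The median difference of all genes moved by over 0.1 with scaling in CDT + DHT (-0.10, and 0.03 with centring) and late G1 against CDT (-0.15, and -0.03 with quantile normalization). Where a value moved, the cause was not tested.

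Counts of genes are given as early G1, late G1, early S, late S or G2/M against CDT unless other arrests (others) are named. Quantile normalization gave 10 in late S and 5 distinct in late G1. Centring gave 11 in early S, 3 in late S against others and 6 distinct in late G1. Without the dimmest 33.3% of genes, which kept all 78 gene calls left to test, there were 56 in late G1, 36 in G2/M, 11 in late S and 8 in G2/M against others, 11 distinct in late G1 and 82 by the F test. With every feature tested there were 4 in early G1, 30 in late G1, 9 in late S, and 8 in late S and 3 in G2/M against others. Trend and robust gave 2 in CDT + DHT, 3 in early G1, 55 in late G1, 12 in early S, 52 in G2/M, 3 in early G1, 12 in late S and 12 in G2/M against others, 16 distinct in late G1, 1 in late S and 120 by the F test, and the androgen-induced list passed in late G1 against CDT + DHT (0.4333). arrayWeights gave 12 in CDT + DHT, 82 in late G1, 205 in late S (106 higher, 99 lower), 58 in G2/M, 377 in late G1, 870 in late S (335 higher, 535 lower) and 25 in G2/M against others, 12 distinct in late G1, 1 in late S and 357 by the F test.

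With only the compared groups in the fit there were 0 in early G1, late G1, early S and late S, 11 in G2/M, 81 in late G1 against others and 14 by the F test. The estimated correlation left the androgen-induced medians at 0.79 in CDT + DHT, 0.81 in late G1, 1.91 in early S, 1.01 in late S and 1.60 in G2/M against CDT, and at 0.92 in early G1, 1.03 in early S, 0.54 in late S and 0.57 in G2/M against CDT + DHT, all no longer past the threshold because the test allows for the correlation of the genes. A pseudocount of 16 gave 4 in CDT + DHT, 13 in early G1 (3 higher, 10 lower), 79 in late G1, 23 in early S, 36 in late S (20 higher, 16 lower), 38 in G2/M, 9 in early G1, 3 in early S, 22 in late S and 18 in G2/M against others, 4 distinct in late G1, 2 in late S and 1 in G2/M, and 117 by the F test. The residual score gave 2 in early G1, 140 in late G1, 14 in early S, 42 in late S, 84 in G2/M, 1 in early G1, 349 in late G1, 9 in late S and 20 in G2/M against others, 16 distinct in late G1 and 145 by the F test. Without 4 arrays there were 0 in early G1, 1 in early S, 2 in late S, 4 in G2/M, 406 in late G1, 1 in late S and 8 in G2/M against others and 2 distinct in late G1, and the G1/S replication list in early_G1 against other arrests reversed (0.002028).

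Same-numbered arrays did not deviate together (median correlation -0.00512 over 57 pairs, -0.0000604 over 114 others), and 7 of 20 arrays lay closest to one of their own number, so the numbers do not pair the arrays. With the replicate block there were 0 in early G1, 5 in late S, 7 in G2/M and 3 in G2/M against others, 57 of the 82 gene calls were kept and no list call changed.

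Leaving out 1 array at a time gave 0 to 2 genes in CDT + DHT, 0 to 1 in early G1, 4 to 26 in late G1, 0 to 4 in early S, 1 to 35 in late S and 3 to 9 in G2/M against CDT, 33 to 230 in late G1, 1 to 13 in late S and 0 to 6 in G2/M against others, 0 to 6 distinct in late G1 and 14 to 58 by the F test. The early S group was then 1 array, assumed to vary like the other groups. The androgen-induced median ran from 0.48 to 0.99 in CDT + DHT, 1.30 to 2.00 in early G1, 0.54 to 0.99 in late G1, 1.42 to 2.27 in early S, 0.78 to 1.52 in late S and 1.41 to 1.71 in G2/M against CDT, and from 0.73 to 1.29, 0.25 to 0.47, 0.73 to 1.69, 0.33 to 0.97 and 0.28 to 0.82 in that order of arrests against CDT + DHT. Medians that reversed are given with their range. Histones in early S ran from -0.03489 (without early S replicate 1) to 1.135 against CDT and from -0.1033 (without the same array) to 1.311 against others. Mitotic genes in late S against CDT ran from -0.1849 (without late S replicate 2; -0.1221 without CDT replicate 1) to 0.8628, and in early G1 from -0.05345 (without CDT replicate 1) to 1.02. Fatty acid synthesis in late S against CDT ran from -0.01901 (without late S replicate 3) to 0.9437. In early G1 against others, replication genes ran from -0.516 to 0.1785 (without early G1 replicate 2) and tubulins from -0.01064 (without early G1 replicate 3) to 0.5732.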

Other observations

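S100P, a calcium-binding protein gene found in several epithelial cancers, was higher than in CDT in early S (5.04 ± 0.81), late S (4.93 ± 0.73) and G2/M (4.50 ± 0.73). Its mean was 2.04 ± 1.80 in CDT, 4.02 ± 0.36 in CDT + DHT, 3.73 ± 1.02 in early G1 and 4.76 ± 0.61 in late G1. TUBA1A, an alpha-tubulin gene, lay at 6.32 ± 0.02 in G2/M and 9.40 ± 0.05 in CDT. It lay at 6.07 ± 0.31 in late G1, where no microtubule drug was used.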
